A study of Mus musculus with 14 samples.

How the data were processed

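RNA from mouse embryonic stem (ES) cells that had differentiated as embryoid bodies was profiled on 14 Affymetrix arrays, 1 per sample. The cells were kept on PMEF feeder cells before differentiation, and complementary DNA was amplified before labelling, per the labels' protocols. The deposited values are log2 expression values for 35556 probe sets, made by the authors with RMA (background correction, quantile normalization between arrays and summary over the probes of a set) in Affymetrix Expression Console, per the submitters' processing notes. The versions of both, and which arrays were normalized together, are not given in the sources used here. RMA forces the arrays towards a common distribution, so a change shared by most genes is lost before these values, and low signals are pulled towards a floor, so the change of a dim gene is understated. Array signals carry no counts, and the number of arrays limits the precision.

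Probe sets were named through the platform annotation. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Symbols were looked up by gene identifier in the RefSeq gene table of GRCm38.p6, which held 21698 of the 21789 probe sets and changed 0 symbols. Where several probe sets shared a symbol, which was the case for 999 genes, the one with the highest mean over the 14 arrays stood for the gene. This left 19938 genes. Positions are not given, since the sources used here name no genome build for the array.

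Groups were taken from the sample labels. The 4 groups with 3 arrays each (control day 2.5, induced 12 h, control day 3 and induced 24 h) were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, group means only), so that the 12 arrays shared 1 estimate of the spread, with 8 residual and 6.05 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were each induced group against the control of the same day, the difference between these 2 effects, and each later group against the earlier one. A line term and its interaction with induction compared iB1 with iEGS. The day 2.25 groups had 1 array each, so their difference is given without a test, and a gene list is set against 10000 random lists of the same size matched on mean expression. All errors of log2 changes are standard errors from limma, and n is 3 arrays per group unless stated.

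The series' design text speaks of independent experiments and the labels number the replicates. Arrays of the same number deviated together from their group means, across genes, with correlations of 0.57, 0.34 and 0.26 between control day 2.5 and induced 12 h, and 0.52, 0.16 and 0.26 between control day 3 and induced 24 h. Replicate 2 of control day 3 correlated up to 0.38 with another number of induced 24 h. Across days the correlations of the same number were 0.56, 0.22 and 0.041 between the control groups and 0.51, -0.0047 and 0.32 between the induced groups. In 4 of the 12 comparisons another number correlated more strongly. The numbers were taken to pair the samples within a day, with less ground for replicate 2. That they also hold across days, which the block over all groups assumes, was clear for replicate 1 only. Replicate 3 is also the only one of the line iB1. The fit with the replicate number as a block leaves 6 residual degrees of freedom.

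A total of 22 gene lists was fixed before the data were examined. Their 469 entries hold 439 different symbols, since some lists share members, so the calls of such lists are not independent. Of these symbols 424 were measured and 15 were not matched to a probe set with 1 symbol. 1 symbol (Spink3) was found under its newer name Spink1. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. The number of members past the test is given over all genes and adjusted over the list alone. Camera compares a list with all other genes. Fry, an alternative, asks only whether the genes of a list move on balance in 1 direction.

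The genes named in the text follow a rule fixed at the same time. They are the induced factors; at 12 h and 24 h the 12 largest rises and 8 largest falls among called genes whose induced arrays all lie on 1 side of the control arrays; up to 4 called members of each called list and 2 members of each other list; at 6 h the 8 largest rises and 4 largest falls among genes whose higher value is above the median of all genes; and for the change of the effect with time, the control days and the lines the 6 largest rises and 6 largest falls past the test. Any other gene named was chosen after its values were seen, as were the further list members given as examples.

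Alternatives were the replicate block, the line as a covariate, quantile normalization again, each array centred on its median, genes below the 40th percentile of mean signal left out, the mean of the probe sets of a gene, all probe sets without collapsing, a trended and robust prior, array weights, only the compared groups in the fit, a fold threshold, an unequal-variance statistic per gene, and the fit without each replicate number and without each array. 2 alternatives were chosen after seeing the data: the gene lists without replicate 3 of the induced 24 h group, and array weights by a gene-by-gene method. For the overlap of the control change with the 24 h effect, the 3 day 3 control arrays were also divided in 6 ways, 1 or 2 of them serving the control change and the others the 24 h effect in a single limma fit. The scripts were tested on simulated data drawn from the means and spreads of the 19938 genes. With simulated log2 changes of 1, the fit called 68% of 50 changed genes at 12 h and 64% of 50 at 24 h. With simulated log2 changes of 2 it called 100% of 50 at each time, and with 0.5 it called 4% at 12 h and 8% at 24 h. In these simulations 4.9% of the calls at 12 h and 1.45% of those at 24 h were unchanged genes. The simulated noise was independent between genes and arrays, with 1 spread per gene for all groups. Pairing, correlated genes and a wider spread in 1 group were thus absent. The runs for 12 h and 24 h differ only in the group that holds the changes and in the noise drawn. These shares thus check the scripts and are no error rates of the real comparisons.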

Results

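Gene expression was measured in mouse ES cells that differentiated as embryoid bodies, cell aggregates in which the first mesoderm, blood and endothelial precursors appear. The cells carried ER71 (the ETS factor encoded by Etv2), GATA2 and, per the sample titles and genotypes, Scl (encoded by Tal1) under control of doxycycline. The design text speaks of 3 factors but names only the first pair, as do the sample descriptions, so Tal1 is treated here as induced on the word of the titles. The series asks which genes and pathways follow their induction on the way to the hemangioblast, a common precursor of blood and endothelium. Doxycycline was given at 1 µg/ml from day 2 to day 3 of differentiation. Induced cells were taken after 6 h (day 2.25, 1 array), 12 h (day 2.5, 3 arrays) and 24 h (day 3, 3 arrays), each with untreated control cells of the same day (1, 3 and 3 arrays). Cells given doxycycline without the factors were not analysed here, so each induction effect includes any effect of doxycycline itself. Replicates 1 and 2 are of the line named iEGS and replicate 3 of a line named iB1. Pairwise correlations between arrays across genes lay between 0.951 and 0.995. Replicate 3 of the induced 24 h group had the lowest mean correlation with the others (0.966, against 0.976 or more for each other array) and the narrowest spread of signal over genes (SD 1.91 on the log2 scale, against 2.04 or more for each other array).

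The induced factors were higher on every doxycycline-treated array than on the control array of the same day and number. Gata2 was at 10.06 after 6 h against 5.68 in the control, and rose by 4.45 ± 0.179 on the log2 scale at 12 h (limma, adjusted p = 1.07e-08) and 3.95 ± 0.179 at 24 h (adjusted p = 1.09e-08). Etv2 was 2.95 higher after 6 h, rose by 3.11 ± 0.192 at 12 h (adjusted p = 6.86e-07) and by 1.94 ± 0.192 at 24 h (adjusted p = 1.47e-05). Tal1 was 2.09 higher after 6 h and rose by 2.48 ± 0.239 at 12 h and 2.30 ± 0.239 at 24 h (adjusted p = 4.9e-05 and 2.4e-05). The effect did not pass the test of a change between 12 h and 24 h for any of them (adjusted p = 0.105 for Etv2, 0.919 for Gata2 and 0.999 for Tal1). The probe sets do not tell the transgene's transcript from that of the cells' own gene, so they do not settle whether Tal1 was induced directly.

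**Figure D1:**
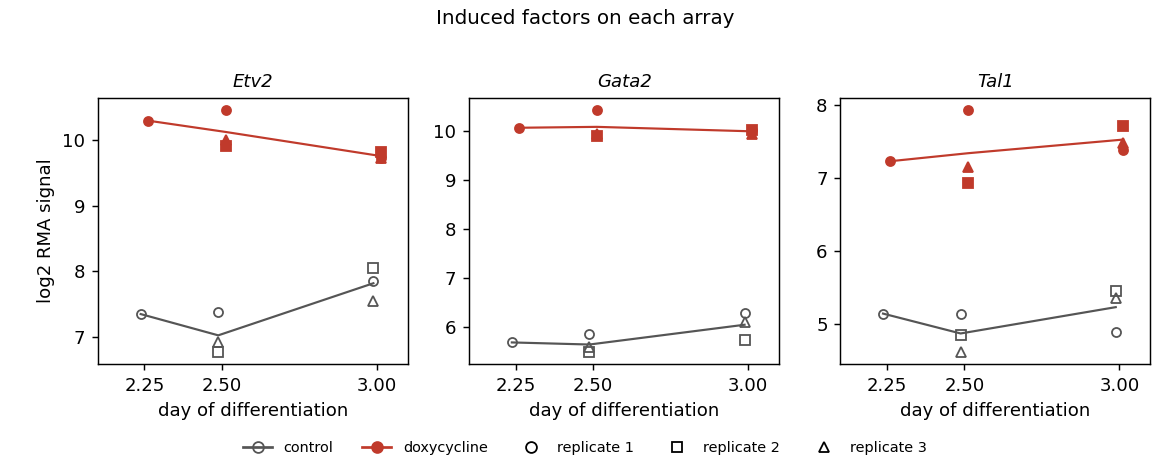
Log2 RMA signal of Etv2, Gata2 and Tal1 (vertical axes) on each of the 14 arrays against the day of differentiation (horizontal axes). Open grey symbols are controls, filled red symbols doxycycline-treated arrays, symbol shapes the replicates and lines join group means. Gata2 lies at 5.68 in the day 2.25 control and at 10.06 after 6 h of doxycycline.

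The earliest difference was read from the day 2.25 arrays. After 6 h, 71 genes differed at least 2-fold, 44 higher and 27 lower than in the control. Beside the 3 factors, the amino acid transporter gene Slc7a8 (11.2-fold), Slc46a3 (4.21-fold), Igfbp4 (3.82-fold), the endothelial transcription factor Sox18 (3.72-fold) and Thsd1 (3.49-fold) were higher. Igfbp3 (4.12-fold), the endoderm and node factor Foxa2 (3.57-fold), Sema6a (3.37-fold) and Wnt8a (3.33-fold) were lower. Of the genes higher at 6 h, 37 of 44 were called higher at 12 h, and 21 of the 27 lower ones were called lower. The endothelial list had a median log2 difference of 0.25, with 6 of 44 members at least 2-fold higher, and lay at percentile 100 of random lists. The VEGF and FGF list (median 0.24) also lay at percentile 100. The primitive streak list (median -0.65) and the epiblast list (median -0.49) lay at percentile 0, with 3 members each at least 2-fold lower. The hypoxia and glycolysis list lay at percentile 0 too, with a smaller median (-0.13) and 0 members 2-fold apart. Low percentiles were also found for the p53 (median -0.15, percentile 0.02), immediate early (-0.17, percentile 0.02), Wnt (percentile 0.33), cardiac (-0.19, percentile 0.47), pluripotency (0.715), paraxial mesoderm (1.37) and primitive erythroid (1.81) lists. The hematopoietic progenitor (98.2) and endoderm (98.5) lists lay high. The 7 remaining lists, the induced factors aside, lay between percentile 5.84 and percentile 93.9. Random lists take no account of genes that vary together. With 1 array per group these differences have no replicate check. In comparison, 16 genes differed at least 2-fold between the day 2.25 and day 2.5 controls of replicate 1, and 63 to 405 between pairs of day 2.5 controls. In a fit that lends the spread of the replicated groups to the lone arrays, 3 genes passed (Gata2, Etv2 and Slc7a8).

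After 12 h of induction, part of the endothelial and blood progenitor genes were higher than in the day 2.5 control. Part of the primitive streak and epiblast genes were lower than in that control. The largest rises after Gata2 were in Slc7a8 (4.03 ± 0.275, 16.4-fold), Etv2, Fli1 (2.85 ± 0.17, 7.21-fold), an ETS factor of blood and endothelium, Nxf7 (2.80 ± 0.149), Npl (2.64 ± 0.161), Sox18 (2.51 ± 0.222), Slc46a3 (2.50 ± 0.211), Tal1, Igfbp4 (2.39 ± 0.19), Slc39a4 (2.38 ± 0.198) and Hhex (2.32 ± 0.213), a homeobox factor of early endoderm and hemangioblasts. The largest falls were in Foxa2 (-2.92 ± 0.226, 7.58-fold), Fst (-2.59 ± 0.192), which encodes the activin antagonist follistatin, Sema6a (-2.46 ± 0.173), Ppp4r4 (-2.43 ± 0.278), Igfbp3 (-2.42 ± 0.224), Wnt8a (-2.34 ± 0.202), Trh (-2.30 ± 0.21) and the microRNA gene Mir363 (-2.09 ± 0.298). Their limma adjusted p-values lay at or below 0.00135. In total 277 of 19938 genes were called, 162 higher and 115 lower, and 168 of them changed at least 2-fold.

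Of the 44 endothelial genes, 17 rose and 0 fell at 12 h (21 and 0 adjusted over the list alone; camera adjusted p = 3.96e-29), among them Fli1, Sox18, Tal1 and Kdr, the VEGF receptor 2 gene (1.96 ± 0.264). Of 29 hematopoietic progenitor genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 1.26e-15), with Gata2, Tal1, Hhex and Lmo2 (1.67 ± 0.264) the largest. Gata2 and Tal1 are induced factors themselves, and without these 6 of 27 rose (adjusted p = 2.23e-10). The endothelial list also holds Tal1, and without it 16 of 43 rose (adjusted p = 7.23e-27). Of 20 primitive streak genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 2.07e-21). The fallers included Foxa2, Fst, Wnt8a and Mesp1 (-1.80 ± 0.232), the earliest cardiac mesoderm factor, and the riser was Amot (1.40), which encodes angiomotin. Of 12 epiblast genes, 4 fell (9 adjusted over the list alone; adjusted p = 3.28e-14), namely Fgf5 (-1.78 ± 0.176), Zic2 (-1.29 ± 0.212), Zic5 (-1.12 ± 0.151) and Sall2 (-1.07 ± 0.165). The calls of these lists held with an estimated correlation, but the camera adjusted p was far larger. It was 0.00299 for the endothelial, 0.00125 for the hematopoietic progenitor, 0.0126 for the primitive streak and 0.00352 for the epiblast list.

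2 signalling lists were called at 12 h with few members past the test. Of 18 BMP pathway genes 2 rose, Bmp4 (1.64 ± 0.154) and Smad6 (0.94 ± 0.194), and 0 fell (6 and 2 adjusted over the list alone; adjusted p = 0.00317, and adjusted p = 0.213 with an estimated correlation). Of 21 genes in the list of Wnt pathway targets 2 fell, Wnt8a and Sp5 (-1.38 ± 0.206), and 1 rose, Lgr5 (1.77 ± 0.273), with 4 fallers and 2 risers adjusted over the list alone (adjusted p = 0.0418, and adjusted p = 0.0974 with an estimated correlation). Beside targets this list holds ligand genes (Wnt3, Wnt3a, Wnt5a, Wnt5b and Wnt8a), the receptor gene Fzd10 and the antagonist genes Sfrp1 and Wif1. It is thus no readout of target genes alone. Wnt8a and Sp5 are also in the primitive streak list. The Wnt call was also lost with the replicate block (adjusted p = 0.0593), without replicate 1 (0.0664), without replicate 3 (0.0949), without replicate 3 of the induced 24 h group (0.0634) and without dim genes (0.136). The VEGF and FGF list was not called (adjusted p = 0.732), with 4 of 24 members higher and 7 lower (7 and 8 adjusted over the list alone), Kdr among the former and Fgf5 among the latter.

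The remaining lists did not pass at 12 h. In the pluripotency list (adjusted p = 0.287) 1 of 25 genes rose and 2 fell (1 and 2 adjusted over the list alone), with Tbx3 at 1.26 ± 0.16, Nanog at -1.61 ± 0.168 and Tdgf1 at -0.64. In the cardiac list (adjusted p = 0.0635) 1 of 21 rose, Tbx20, and 2 fell, Mesp1 and Actc1 (-1.25 ± 0.214), with 1 and 3 adjusted over the list alone. In the endoderm list (adjusted p = 0.0719) 2 of 25 rose, Sox7 (1.87 ± 0.207) and Apoe, and 1 fell, Foxa2 (5 and 2 adjusted over the list alone). Hey1 rose by 1.96 ± 0.153 in the Notch list (1 of 15 higher and 0 lower, 1 and 1 adjusted over the list alone, adjusted p = 0.0635). Dll3 fell by 0.74 in the paraxial mesoderm list (1 of 19 lower, 2 adjusted over the list alone, adjusted p = 0.253). Jun rose by 0.84 in the immediate early list (1 of 16 higher, also adjusted over the list alone, adjusted p = 0.111), and Slc7a5 by 0.72 in the ATF4 list (1 of 26 higher, also adjusted over the list alone, adjusted p = 0.127). No member passed over all genes in the primitive erythroid (14 genes, adjusted p = 0.566), neuroectoderm (14 genes, 0.732), cell cycle (27 genes, 0.476), p53 (17 genes, 0.874) and hypoxia and glycolysis (27 genes, 0.779) lists, and none passed adjusted over the list alone. The fibroblast feeder (23 genes, adjusted p = 0.0635) and smooth muscle (13 genes, adjusted p = 0.0635) lists also had no member past the test over all genes, and 1 each adjusted over the list alone. With the replicate block, Thy1 of the former (1.02, limma adjusted p = 0.00176) and Cnn1 of the latter (-0.62, 0.0319) passed over all genes. Some of these lists passed under an alternative. Without replicate 2 the cardiac (adjusted p = 0.0383), Notch (0.0469), fibroblast feeder (0.0392) and smooth muscle (0.0392) lists passed, and without dim genes the fibroblast feeder (0.00828) and endoderm (0.0172) lists. With fry the Notch list passed (adjusted p = 0.0124). The labels place PMEF feeder cells in the culture before differentiation. Median and mean differed in sign in the neuroectoderm list (0.02 and -0.04) and the p53 list (-0.04 and 0.01).

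With the replicate number as a block the fit called 441 genes at 12 h, 247 higher and 194 lower, and all 277 genes were among them. Without replicate 2 the count was 80, without replicate 3 it was 103, and without replicate 1 or replicate 3 of the induced 12 h group it was 177 or 179. Of the genes named at 12 h, 3 lost their call without replicate 1 (Dll3, Smad6 and Slc7a5), 11 without replicate 2 (Mir363, Kdr, Lmo2, Actc1, Dll3, Zic2, Zic5, Sall2, Lgr5, Slc7a5 and Jun, with limma adjusted p between 0.0593 and 0.462) and 11 without replicate 3 (Lmo2, Actc1, Dll3, Tbx3, Zic2, Sall2, Lgr5, Sp5, Smad6, Slc7a5 and Jun, between 0.0578 and 0.574).

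After 24 h of induction, most of the endothelial genes measured were higher than in the day 3 control. Primitive streak, epiblast and part of the mesoderm genes were lower than in that control. The primitive streak, cardiac and paraxial mesoderm lists had themselves risen in the controls since day 2.5. A fall against the day 3 control can thus be a missing rise. For the primitive streak list, the mean change at 24 h (-2.19) was larger in size than the mean rise in the controls (0.869). This argues against a missing rise alone for that list. The mean changes were -0.797 at 24 h and 0.709 in the controls for the cardiac list, and -0.39 and 0.511 for the paraxial list. Fli1 (4.27 ± 0.17, 19.3-fold), Npl (4.22 ± 0.161), the angiopoietin receptor gene Tek (4.10 ± 0.296, 17.2-fold), Gata2, Sox7 (3.92 ± 0.207), the VE-cadherin gene Cdh5 (3.42 ± 0.23, 10.7-fold), Slc7a8 (3.30 ± 0.275), Kcne3 (2.96 ± 0.301), Ripor2 (2.96 ± 0.244), Zfp711 (2.86 ± 0.232), Nxf7 (2.79 ± 0.149) and Esam (2.75 ± 0.194), an endothelial adhesion molecule, rose most. Cer1 (-5.28 ± 0.319, 38.8-fold), which encodes the nodal and BMP antagonist cerberus of the anterior endoderm, fell most, followed by Fst (-4.55 ± 0.192), Mesp1 (-4.36 ± 0.232, 20.5-fold), Lhx1 (-3.96 ± 0.3), Frzb (-3.89 ± 0.326), Mixl1 (-3.85 ± 0.254), Asb4 (-3.76 ± 0.16) and Fgf5 (-3.63 ± 0.176). The limma adjusted p-values of these genes were 1.93e-05 or lower. In total 1088 genes were called, 405 higher and 683 lower, and 459 changed at least 2-fold. The shared spread assumes groups that vary alike. The root mean square log2 difference between 2 arrays of a group was 0.371 to 0.615 for induced 24 h. It was 0.236 to 0.31 for induced 12 h, 0.296 to 0.416 for control day 2.5 and 0.262 to 0.326 for control day 3. Errors at 24 h may thus be understated. With only the compared groups in the fit, 669 genes were called at 24 h and 300 at 12 h.

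Of the 44 endothelial genes, 26 rose and 1 fell at 24 h (31 and 1 adjusted over the list alone; camera adjusted p = 2.52e-35). The faller was the apelin receptor gene Aplnr (-1.48), the gene that rose most between the control days. Kdr did not pass at 24 h (0.62, adjusted p = 0.252), and its effect did not pass the test of a change from 12 h (adjusted p = 0.247). Of 29 hematopoietic progenitor genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 4.69e-19), with Gata2, Tal1, Lmo2 (2.04 ± 0.264) and Runx1 (1.72 ± 0.188) as the largest. Without the induced factors 14 of 27 of these and 25 of 43 endothelial genes rose (adjusted p = 2.05e-15 and 3.25e-34). With an estimated correlation the camera adjusted p was 0.00165 for the full endothelial list and 0.00117 for the full hematopoietic progenitor list. In the primitive erythroid list 3 of 14 genes rose, Nfe2 (1.53 ± 0.216), Gata1 (0.90 ± 0.198) and Epor (0.59 ± 0.151), also 3 adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.368 with an estimated correlation, adjusted p = 0.0838 with fry, adjusted p = 0.209 without replicate 3 of the induced 24 h group, and adjusted p = 0.0997 without replicate 3). The embryonic globin gene Hbb-bh1 lay at a mean of 2.87 at 24 h and 2.88 in the control.

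Of 20 primitive streak genes, 17 fell and 0 rose at 24 h (18 and 0 adjusted over the list alone; adjusted p = 1.46e-34), led by Fst, Mesp1, Lhx1 and Mixl1. Of 12 epiblast genes, 10 fell (also 10 adjusted over the list alone; adjusted p = 4.69e-19), among them Fgf5, the N-cadherin gene Cdh2 (-3.41 ± 0.224), Zic2 (-2.69 ± 0.212) and Otx2 (-2.21 ± 0.158). With an estimated correlation the camera adjusted p was 0.00342 for the primitive streak list and 0.00165 for the epiblast list. Of 21 cardiac mesoderm genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 5.47e-07, and adjusted p = 0.0864 with an estimated correlation), with Mesp1, Pdgfra (-2.78 ± 0.211), Actc1 (-2.41 ± 0.214) and Myl7 (-2.08 ± 0.169). Of 19 paraxial mesoderm genes, 8 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.000267, and adjusted p = 0.00898 with an estimated correlation), with Mesp2 (-1.88 ± 0.174), Msgn1 (-1.43 ± 0.191), Dll3 (-1.39 ± 0.172) and Tbx6 (-1.03 ± 0.176), and the riser was Cited1 (0.83). Of 13 smooth muscle genes, 3 fell (also 3 adjusted over the list alone; adjusted p = 0.0397, adjusted p = 0.327 with an estimated correlation, adjusted p = 0.0954 without replicate 2, and adjusted p = 0.0709 without dim genes), Cnn1 (-1.88 ± 0.174), Myl9 (-1.15 ± 0.18) and Tagln (-0.99 ± 0.255).

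Of 21 genes in the Wnt list, 8 fell and 1 rose at 24 h (9 and 1 adjusted over the list alone, camera adjusted p = 6.54e-05, and adjusted p = 0.00593 with an estimated correlation). The largest falls were in Sp5 (-3.03 ± 0.206), the ligand gene Wnt8a (-2.16 ± 0.202), Lef1 (-1.84 ± 0.193) and the ligand gene Wnt5a (-1.80 ± 0.212). The riser was Lgr5 (1.70). In the VEGF and FGF list 8 of 24 genes fell and 2 rose (8 and 4 adjusted over the list alone; adjusted p = 0.0182, adjusted p = 0.407 with an estimated correlation, adjusted p = 0.0674 without replicate 1, and adjusted p = 0.183 without dim genes). Its median was -0.03, and -0.0148 with quantile normalization again. It turned to 0.000545 when arrays were centred, which moves all genes alike. The largest fallers were the ligand gene Fgf5 and Etv5 (-2.74 ± 0.235), Dusp6 (-2.43 ± 0.189) and Spry4 (-2.01 ± 0.214), targets and feedback inhibitors of FGF signalling. The risers were the VEGF receptor genes Flt1 (1.17) and Flt4 (1.06), which are also in the endothelial list. The BMP list was not called (adjusted p = 0.933), with 3 of 18 genes higher, led by Id2 (1.54 ± 0.174) and Bmp4 (1.49 ± 0.154), and 7 lower (5 and 7 adjusted over the list alone). In the Notch list (adjusted p = 0.945) 2 of 15 rose, Hey1 (0.92 ± 0.153) among them, and 4 fell, with Jag1 (-2.12 ± 0.199) the largest (2 and 4 adjusted over the list alone).

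The pluripotency list did not pass at 24 h (adjusted p = 0.146), with 4 of 25 genes lower, led by Tdgf1 (-2.17 ± 0.133) and Nanog (-1.99 ± 0.168), and 1 higher (5 and 2 adjusted over the list alone). In the endoderm list (adjusted p = 0.916) 5 of 25 genes rose, led by Sox7, which is also an endothelial gene, and 4 fell, led by Cer1 (5 and 6 adjusted over the list alone). Nes (-1.18 ± 0.286) and Ncam1 (-0.74 ± 0.167) fell in the neuroectoderm list (2 of 14 lower, also adjusted over the list alone, adjusted p = 0.916). In the p53 list (adjusted p = 0.916) Eda2r rose by 1.29 ± 0.257, and Pmaip1 (-1.15 ± 0.132) was 1 of 2 fallers among 17 genes, with the same counts adjusted over the list alone. The ATF4 list (adjusted p = 0.446) had 2 of 26 genes higher, with Slc7a5 at 0.84 ± 0.159, and 1 lower, Vldlr at -0.92 ± 0.202, as it did adjusted over the list alone. In the hypoxia and glycolysis list (adjusted p = 0.811) Egln3 rose by 0.64 ± 0.147 and Ndrg1 fell by 1.87 ± 0.215 among 27 genes (2 and 2 adjusted over the list alone). The fibroblast feeder list (adjusted p = 0.916) had 1 of 23 genes higher, Thy1 at 0.98 ± 0.251, also adjusted over the list alone, and the immediate early list (adjusted p = 0.863) had 2 of 16 higher, Jun at 0.87 ± 0.158 and Atf3 at 0.80 ± 0.151, and 1 lower (2 and 5 adjusted over the list alone). None of 27 cell cycle genes passed, over all genes or adjusted over the list alone (adjusted p = 0.0669). The list passed with the replicate block (adjusted p = 0.0437) and without replicate 1 (0.00928), and had an adjusted p of 0.922 with an estimated correlation, which was 0.62 between its genes. Median and mean differed in sign in the BMP list (0.15 and -0.04, camera upwards), the endoderm list (0.13 and -0.28, camera downwards), the neuroectoderm list (0.03 and -0.08, camera downwards) and the Notch list (0.03 and -0.08, camera downwards). In the p53 list both were below 0 while camera pointed upwards, and its median turned from -0.01 to 0.10 with quantile normalization again and to 0.02 with centred arrays. The median of the hypoxia and glycolysis list turned from -0.02 to 0.00664 and 0.00885.

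Lower genes made up 62.8% of the calls at 24 h, and 52.9% (519 of 982, with 463 higher) without replicate 3 of the induced 24 h group, the array with the narrowest signal spread. The count was 392 without replicate 2, 476 without replicate 3, and 1889 without replicate 1 of the induced 24 h group. Of the genes named at 24 h, Ncam1 lost its call without replicate 1. Without replicate 2, 13 lost it (Gata1, Epor, Nes, Ncam1, Hey1, Eda2r, Vldlr, Slc7a5, Egln3, Thy1, Tagln, Jun and Atf3, with limma adjusted p between 0.089 and 0.435). Without replicate 3, 11 did (Gata1, Epor, Nes, Ncam1, Vldlr, Slc7a5, Egln3, Thy1, Myl9, Tagln and Atf3, between 0.0575 and 0.361).

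**Figure D2:**
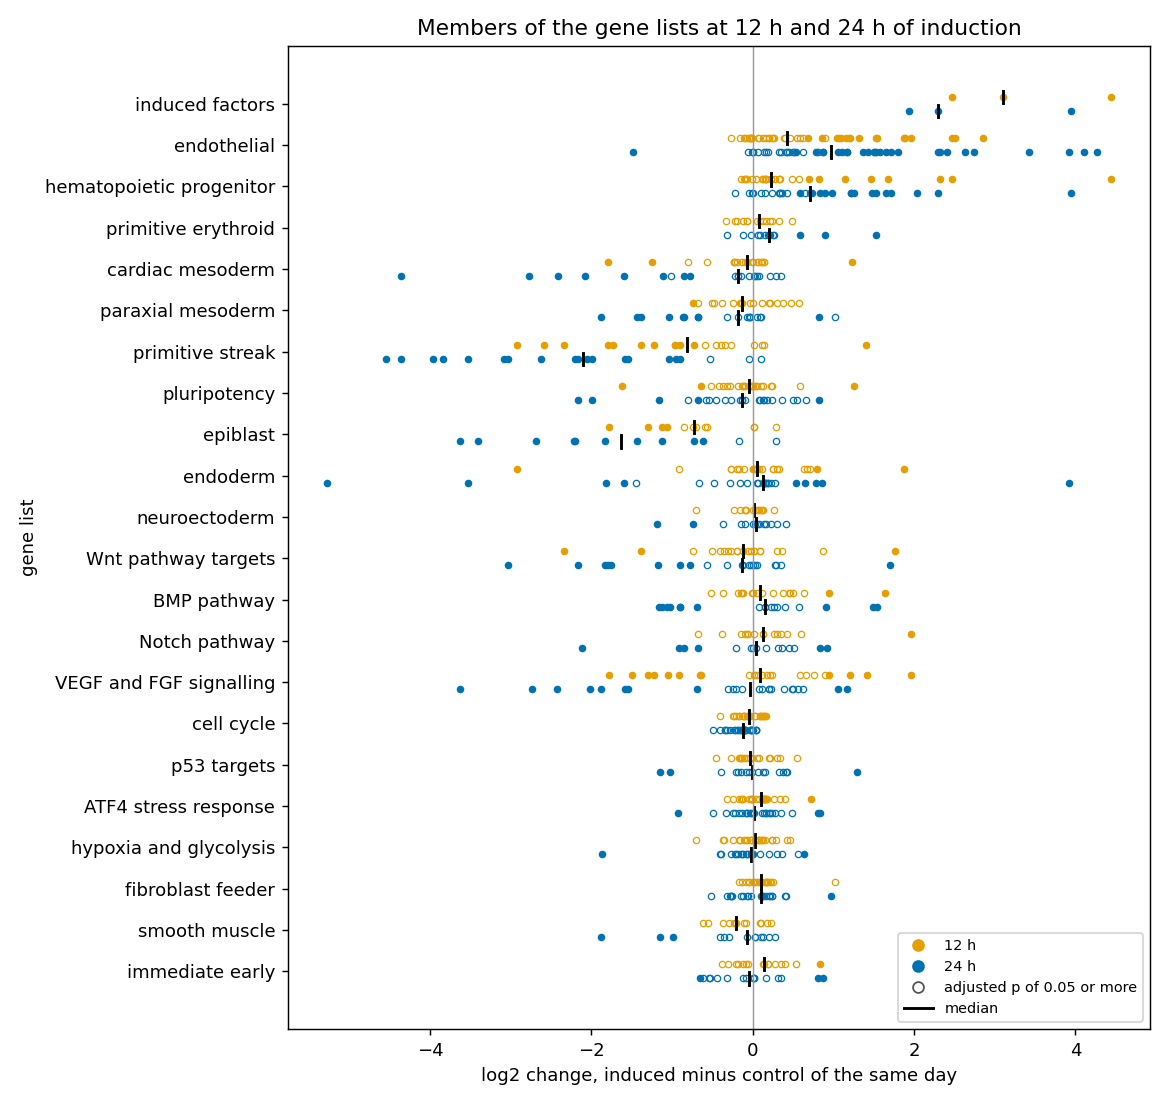
Log2 change of each measured member of the 22 gene lists (rows) at 12 h (orange) and 24 h (blue), as induced minus control of the same day on the horizontal axis. Filled points have a limma adjusted p under 0.05, open points do not, and black bars are medians. The median of the primitive streak list moved from -0.81 at 12 h to -2.11 at 24 h, and that of the endothelial list from 0.43 to 0.96.

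The calls at both times overlapped. Of the genes higher at 12 h, 118 of 162 were also called higher at 24 h, where independent lists of these sizes would share 3.29. Of the genes lower at 12 h, 106 of 115 were called lower at 24 h (3.94 for independent lists), and 0 genes were called in opposite directions. The control arrays of the 2 times are different arrays.

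The change of the induction effect between 12 h and 24 h was tested directly. The effect rose for the protease inhibitor gene Ctla2a (by 2.86 ± 0.302 on the log2 scale, adjusted p = 0.000862), Tek (2.58 ± 0.418), Cdh5 (2.26 ± 0.325), Ctla2b (2.15 ± 0.372), Ptprb (2.08 ± 0.4), which encodes the vascular endothelial phosphatase VE-PTP, and Sox7 (2.05 ± 0.293). It fell most for Cer1 (-4.37 ± 0.451), Lhx1 (-3.51 ± 0.424), Frzb (-2.90 ± 0.461), Dgkk (-2.88 ± 0.465), the nodal co-receptor gene Cfc1 (-2.83 ± 0.241) and Cdh2 (-2.70 ± 0.317), with limma adjusted p-values of 0.0344 or lower for all 12. In total 85 genes were called, 20 with a larger and 65 with a smaller or more negative effect at 24 h. With the replicate block 163 genes were called (36 and 127). After quantile normalization again the count was 130 (48 and 82, so 63.1% lower against 76.5%). Without replicate 2 it was 4, without replicate 3 it was 2, and it was 48 without any one of replicate 1 of control day 3 and replicates 2 and 3 of the induced 12 h group. Of the 12 genes named, Cer1, Lhx1 and Cfc1 kept their call without replicate 2 and Ctla2a kept its call without replicate 3.

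The change with time was also tested for the lists. The effect on the endothelial list moved upwards (5 of 44 members higher and 0 lower, 13 and 2 adjusted over the list alone, camera adjusted p = 4.78e-17). So did that on the hematopoietic progenitor list (0 of 29 called with limma, 3 higher adjusted over the list alone, adjusted p = 0.000437). It moved downwards for the primitive streak list (8 of 20 lower, 12 adjusted over the list alone, adjusted p = 3.1e-26) and the epiblast list (4 of 12, 7 adjusted over the list alone, 1.9e-14). The cardiac (4 of 21, 7 adjusted over the list alone, 5.38e-09), VEGF and FGF (3 of 24, 6 alone, 6.83e-08), Wnt (3 of 21, 5 alone, 0.000465) and paraxial mesoderm (1 of 19, 5 alone, 0.000465) lists moved downwards too. These 8 calls held with an estimated correlation (camera adjusted p between 0.0126 and 0.0493). The downward calls of the induced factors (adjusted p = 0.00611), BMP (0.0218) and Notch (0.0202) lists and the upward call of the erythroid list (0.0112) did not (adjusted p = 0.143, 0.302, 0.0747 and 0.302 with an estimated correlation).

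Controls of day 3 and day 2.5 show what differentiation without doxycycline did over the same interval. Aplnr (3.04 ± 0.305, 8.25-fold), Spink1 (3.00 ± 0.479), Asb4 (2.69 ± 0.16), Lhx1 (2.62 ± 0.3), Mesp1 (2.54 ± 0.232) and Cfc1 (2.46 ± 0.17) rose most, and Cbr3 (-1.41 ± 0.283), Uchl1 (-1.40 ± 0.229), Tmem54 (-1.40 ± 0.224), Slc7a3 (-1.37 ± 0.167), H2ac1 (-1.36 ± 0.208) and the TGF-beta family gene Gdf3 (-1.33 ± 0.219) fell most (limma adjusted p = 0.0324 or lower). The primitive streak list rose with 8 of 20 members (12 adjusted over the list alone, camera adjusted p = 3.81e-22) and the cardiac list with 6 of 21 (10 adjusted over the list alone, 4.65e-18). The paraxial mesoderm (5 of 19, 8 alone, 1.43e-11), endoderm (6 of 25, 7 alone, 7.6e-09), BMP (6 of 18 higher and 1 lower, 10 and 2 alone, 1.43e-11), Wnt (3 of 21, 4 alone, 6.63e-06) and Notch (3 of 15, 5 higher and 1 lower alone, 0.000453) lists rose too. The calls of these rising lists held with an estimated correlation (camera adjusted p between 0.00133 and 0.0169). The pluripotency list moved downwards (2 of 25 lower and 1 higher, 3 and 1 adjusted over the list alone, adjusted p = 1.72e-06, and adjusted p = 0.24 with an estimated correlation). The upward calls of the induced factors (adjusted p = 0.000508) and VEGF and FGF (1.37e-05) lists and the downward call of the ATF4 list (0.000204) were lost as well (adjusted p = 0.0844, 0.0957 and 0.0844 with an estimated correlation). In total 151 genes were called, 112 higher and 39 lower, and 344 (197 and 147) with the replicate block. The count was 21 without replicate 2 and 17 without replicate 3. It was 75 and 87 without replicates 2 and 3 of control day 2.5, and 93 and 67 without replicates 2 and 3 of control day 3. The calls of Spink1, Uchl1, Tmem54, H2ac1 and Gdf3 were lost without replicate 2 and without replicate 3, and those of Cbr3 and Slc7a3 without replicate 2.

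Of the 112 genes that rose in the controls, 76 were lower at 24 h of induction than in the day 3 control and 9 were higher. Asb4, Lhx1, Mesp1 and Cfc1 were among the 76. Both comparisons use the day 3 control arrays. Independent lists of these sizes would share 3.84. In 50 simulations without an induction effect against shared controls, a mean of 0.02 genes and at most 1 were shared. These simulations do not give the part that shared controls add beside an effect. Part of the excess may thus still come from the shared day 3 control arrays. With these arrays divided so that none served in both comparisons, 7 to 38 genes were shared in 6 divisions (0.172 to 1.08 for independent lists). Across all genes the covariance of the 2 changes was -0.0225, against a mean of -0.0216 in 50 simulations without an induction effect against shared controls, and -0.0239 to 0.00967 in the divisions.

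Within the induced arrays, the epiblast list fell from 12 h to 24 h with 6 of 12 members (11 adjusted over the list alone, camera adjusted p = 3.08e-14). The endothelial list rose with 15 of 44 members (23 adjusted over the list alone, adjusted p = 4.31e-25). The hematopoietic progenitor list rose with 4 of 29 members higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 1.51e-07). The epiblast, endothelial and hematopoietic progenitor calls held with an estimated correlation (camera adjusted p = 0.00734, 0.00734 and 0.0109). In the pluripotency list 6 of 25 members fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 1.51e-07, and adjusted p = 0.217 with an estimated correlation). Calls of 7 further lists were lost in the same way. The primitive streak, cell cycle, ATF4 and immediate early lists had moved downwards (adjusted p = 0.000116, 0.0182, 0.00177 and 0.00505, and adjusted p = 0.217, 0.752, 0.198 and 0.198 with an estimated correlation). The erythroid, endoderm and BMP lists had moved upwards (adjusted p = 0.00253, 0.00103 and 0.000873, and adjusted p = 0.217, 0.198 and 0.198 with an estimated correlation). The cardiac and paraxial mesoderm lists, lower at 24 h than in the control, were not called here (camera adjusted p = 0.245 and 0.105). In the cardiac list 0 of 21 members passed (1 higher and 1 lower adjusted over the list alone). In the paraxial list 3 of 19 were higher and 0 lower, also adjusted over the list alone. In total 360 genes were called, 111 higher and 249 lower (69.2% lower). The count was 445 (197 and 248, 55.7% lower) after quantile normalization again and 742 (240 and 502) with the replicate block. It was 21 without replicate 2 (7 and 14) and 53 without replicate 3 (32 and 21, 39.6% lower). Without replicate 1 of the induced 24 h group it was 727 (230 and 497, 68.4% lower). Without replicate 3 of that group it was 269 (122 and 147, 54.6% lower). Without replicate 1, 2 or 3 of the induced 12 h group it was 179, 161 or 165.

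**Figure D3:**
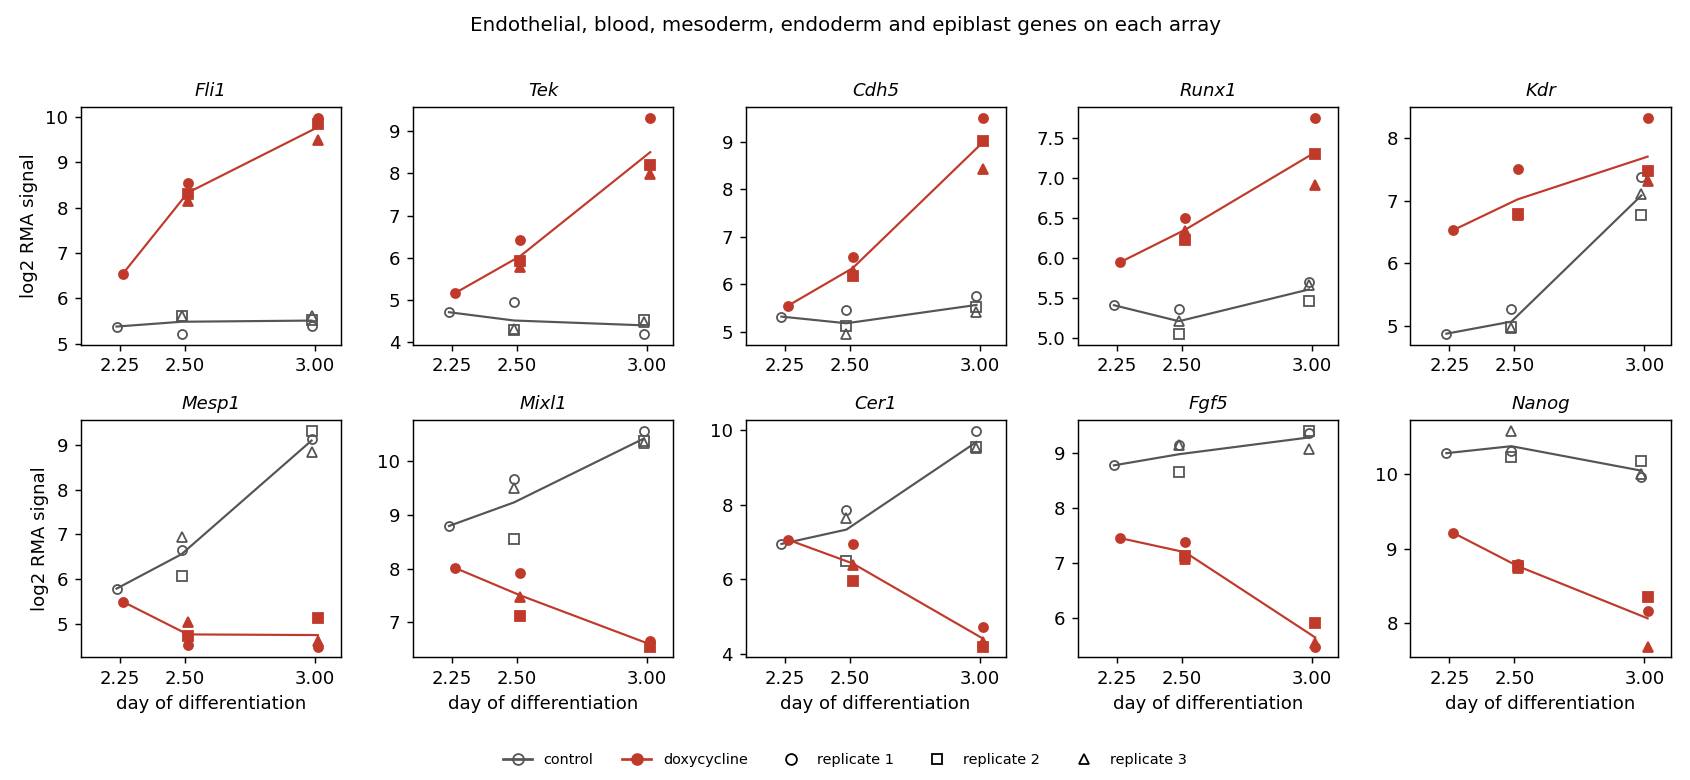
Log2 RMA signal of 10 genes (vertical axes) on each of the 14 arrays against the day of differentiation (horizontal axes), with symbols and lines as in the plot of the induced factors. Mesp1 rose in the controls from a mean of 6.56 at day 2.5 to 9.10 at day 3 and lay at 4.75 after 24 h of doxycycline, and Kdr reached a mean of 7.09 in the day 3 controls.

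A difference of the induction effect between the lines was not detectable. With limma, 0 of 19938 genes passed for the difference between iB1 and iEGS, and 519 had an unadjusted p under 0.05. That is fewer than a share of 0.05 of all genes, which unchanged genes would give on average. This fit holds no replicate block, so deviations shared by arrays of replicate 1 or of replicate 2 stay in its spread. The test can thus miss differences. The line iB1 is 1 experiment with 4 arrays here, so line and experiment cannot be told apart.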

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

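The tests of what sets replicate 3 of the induced 24 h group apart, of the shared controls, of delayed differentiation and of the paired splits for the change with time were chosen only after those results had been seen. Leaving that array out was planned. The change of the induction effect with time stood out because a direct test found 85 genes whose effect differed between 12 h and 24 h. The difference of the log2 effect was 2.86 for Ctla2a, 2.58 for Tek, 2.26 for Cdh5, 2.15 for Ctla2b, 2.08 for Ptprb and 2.05 for Sox7. It was -4.37 for Cer1, -3.51 for Lhx1, -2.90 for Frzb, -2.88 for Dgkk, -2.83 for Cfc1 and -2.70 for Cdh2. Signals also appeared in probe sets that were not used for genes. At 12 h, 5 of 1621 probe sets with several symbols and 7 of 12146 unlisted probe sets passed the test, and at 24 h 13 and 78 did.

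Replicate 3 of the induced 24 h group stood apart from the other 2 arrays of its group. Over the 18650 genes called in no comparison, its deviation from these arrays had a slope of -0.114 on their mean level, against -0.0732 to 0.0737 for the other 11 arrays. These slopes correlated with the spread of signal over genes across the 12 arrays (0.904), so they restate its narrow spread, and a compressed signal range cannot be told apart from another cause of it. In 1 of the 3 other groups the iB1 array deviated together with it more strongly than the replicate 2 array did. A constant property of the line iB1 stays open, since the line is 1 experiment.

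Lower genes made up 62.8% of the calls at 24 h (683 lower and 405 higher). Without that array they made up 52.9% (519 lower and 463 higher), and without replicate 1 or replicate 2 of the same group 65% and 64.4%. This is consistent with that array as a source of part of the excess. Quantile normalization again gave 54.8% (715 lower and 590 higher), a smaller share through more higher genes and not through fewer lower ones, and centring each array on its median gave 57.7% (604 and 442). A biological excess of falling genes stays open and was not tested apart from this.

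Genes that rose in the controls from day 2.5 to day 3 were often lower at 24 h of induction (76 of 112). With the day 3 control arrays divided so that none served in both comparisons, 7 to 38 genes were shared in 6 divisions, against 0.172 to 1.08 for independent lists, which argues against the shared controls as the only cause for these called genes. Independent lists are a weak yardstick, since undivided controls exceeded them in other directions too. Of the risers 9 were higher at 24 h (2.28 for independent lists), and of the genes that fell in the controls 11 were lower (1.34) and 5 higher (0.792). Across all genes the covariance (-0.0225) lay near that simulated from shared controls without an induction effect (-0.0216). A delay of differentiation as the only cause would hold up the 39 genes that fell in the controls as strongly, by 0.79 at 24 h. Their median change was -0.153, with a bootstrap interval over genes from -0.463 to 0.0565. Resampling takes the genes as independent and carries no variation between arrays, so the interval is likely too narrow. With other scaling or without 1 replicate or array, the needed value lay between 0.666 and 0.837. The median change then lay between -0.262 and -0.0275. In addition 23 of the 39 genes were also called lower from 12 h to 24 h in the induced arrays (0.487 for independent lists). These values argue against a delay as the only cause. A part played by a delay cannot be told apart from a fall of these lineage genes alone, since that interval includes 0.

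Other splits of the arrays were fitted for each comparison. The 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 277 calls at 12 h, 1088 at 24 h, 151 between control days and 360 between induced times. It was the only 1 of 10 with as many in each case, the highest of the other splits giving 0 with limma, also among the splits that part all 3 pairs. Mixed splits move the real effect into the spread, which lowers their own counts, so these 0 calls do not bear on chance. For the change of the effect with time, 4 of 100 drawn splits, the real one included, gave at least the real 85 calls, a share under 0.05. Of the 14 drawn splits that part all 3 pairs on both days, 2 did, with 150 calls in the highest other. The highest of all gave 305. The splits with 305 and 150 calls keep the day 3 groups and exchange 2 of the 3 labels per group at day 2.5, which adds part of the real 12 h effect to the 24 h effect. The split with 103 calls exchanges these at day 2.5 and mirrors the day 3 groups. Such exchanged splits still hold the real induction effect, so they do not show what chance alone would give. The real split gave 4 calls without replicate 2 and 2 without replicate 3, so whether chance can be excluded for its count stays open. For the line difference, 3 of 3 choices of the odd replicate number gave 0 calls, which are too few choices for a share under 0.05.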

How the results depend on the processing

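The gene-by-gene array weights and the lists without replicate 3 of the induced 24 h group were chosen only after the data had been seen. The counts were 277 (12 h), 1088 (24 h), 85 (difference of the effects), 151 (control days), 360 (induced times), 71 (6 h) and 18 of 44 list tests. In the order of the first 5, the replicate block gave 441, 1565, 163, 344 and 742 genes. Default array weights gave 1885, 467, 48, 1350 and 89. Their estimate stopped before convergence and gave 1 array a weight of 2.5e-05. Gene-by-gene weights gave 798, 2634, 318, 471 and 1495. The unequal-variance statistic, which shares no spread between genes, gave 0, 1, 0, 0 and 0, with 1359, 1777, 853, 1140 and 1201 genes at an unadjusted p under 0.05. A threshold of 2-fold left 168 genes at 12 h and 459 at 24 h, and the iEGS arrays alone, which are fewer, 103 and 476. With only the compared groups in the fit, the count was 669 at 24 h and 100 between induced times. All probe sets without collapsing gave 39 for the difference, 71 between control days and 174 between induced times. Quantile normalization again gave 130 for the difference. For the weights, the block, the compared groups, the probe sets and the quantile normalization the cause was not tested. At 6 h a log2 threshold of 1.5 left 21 genes and the pooled-spread fit, which assumes that the lone arrays vary like the others, 3. Leaving out 1 replicate number or array gave 80 to 222 genes at 12 h, 392 to 1889 at 24 h, 2 to 109 for the difference, 17 to 189 between control days, 21 to 727 between induced times and 16 to 21 list calls. The line difference stayed at 0 with limma in its 5 alternatives, none of which adds the replicate block (519 genes at an unadjusted p under 0.05 in the fit as planned). List calls numbered 12 with an estimated correlation, 18 with fry, 18 with the block, 17 without dim genes and 16 without replicate 3 of the induced 24 h group. Without the 3 factors they numbered 16 of 42 tests, since the list of the factors drops out, and 0 other calls were lost. The block changed the calls of the Wnt list at 12 h and the cell cycle list at 24 h. It also called the endoderm list downwards for the change with time (camera adjusted p = 0.0417, against 0.0779). Between the control days it called the endothelial list upwards (0.0424, against 0.0625). Of 147 named gene results, 147 kept their direction and their side of the threshold after quantile normalization again and with the mean of the probe sets. With the block 145 did, with Thy1 and Cnn1 gained at 12 h, and 141, 107 and 109 did without replicate 1, 2 and 3. Scaling turned the sign of 3 list medians at 24 h. Centring moves all genes alike (median over all genes from -0.00404 to 0.0291), so its turns do not bear on a list relative to other genes. That of the called VEGF and FGF list went from -0.0326 to 0.000545 with centred arrays. With quantile normalization again and with centring, that of the p53 list went from -0.014 to 0.0971 and 0.0191, and that of the hypoxia and glycolysis list from -0.0242 to 0.00664 and 0.00885. Signals near the background limit what can be read for dim genes such as Hbb-bh1.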

Other observations

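The tests of interferon genes, of the region of Hprt and of X-linked genes were chosen after the calls had been seen, and the genes in this part were chosen after their values were seen. The microRNA genes of the miR-302 and miR-367 cluster, abundant in pluripotent cells, fell together at 24 h. Of the miR-290 to miR-295 group 0 genes were measured. The miR-302 and miR-367 genes lie in 1 cluster, so their calls are not independent observations. All 5 measured members were called lower (median -2.27; Mir302b -1.60 ± 0.229, limma adjusted p = 0.00043), 0 were called at 12 h with limma (0 at an unadjusted p under 0.05), and the test of the difference between 24 h and 12 h passed for Mir302b (adjusted p = 0.0398) and Mir302c (0.0163), which lay at 0.0451 and 0.208 at 12 h. Neither difference passed without replicate 2 (adjusted p = 0.639 and 0.754) or without replicate 3 (0.694 and 0.309). The 24 h calls of Mir302a (0.215), Mir302d (0.106) and Mir367 (0.106) were lost without replicate 2, and that of Mir367 (0.0659) without replicate 3. Of 9 feedback inhibitors and targets of FGF signalling, 4 were called lower at 12 h and 8 at 24 h (median -1.88; Etv5 -2.74, Dusp6 -2.43, Spry4 -2.01, Il17rd -1.96). They were not tested as a set, and the VEGF and FGF list fixed beforehand lost its call at 24 h with an estimated correlation (adjusted p = 0.407), without dim genes (0.183) and without replicate 1 (0.0674). Without replicate 3 of the induced 24 h group 5 and 7 members were called lower. The directions held after quantile normalization again (medians -2.31 and -1.85) and after centring each array (-2.23 and -1.84).

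Some genes of interferon response and antigen processing were lower after induction. Irf1 fell by 1.36 ± 0.197 at 12 h and by 2.09 ± 0.197 at 24 h (limma adjusted p = 0.00162 and 9.56e-06), and Psmb8 of the immunoproteasome fell by 1.31 and 2.06. All 9 genes first noticed were called lower at 12 h and 8 of them at 24 h. Whether the fall extends beyond them was tested on 19 other measured members of the group. At 12 h limma called 0 of these (7 lower and 0 higher at an unadjusted p under 0.05). Camera gave p = 0.00286 for a lower list at 24 h (p = 0.0272 with an estimated correlation), with 4 of 19 called lower and a median of -0.227 (3 lower with each array centred, and 3 without replicate 3 of the induced 24 h group). This is consistent with a fall of part of the group. Psmb9 (-0.918), Tap2 (-0.499), Psme2 (-0.809) and Cxcl10 (-0.905) fell, while Ifit1 (-0.0255) and Stat2 (-0.175) did not pass. The change was above 0 for 6 of the 19, Ifit3 (0.442), Oas1a (0.392) and Nlrc5 (0.293) the highest, and none of these passed. No doxycycline-treated array without the factors was analysed here, so an effect of doxycycline itself was not tested.

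Hprt, a housekeeping gene used in several doxycycline-inducible ES lines as the insertion site of the transgene, rose by 1.67 ± 0.252 at 24 h (limma adjusted p = 0.000697; 0.75 at 12 h, adjusted p = 0.299). The labels do not say where the transgenes sit in these lines. Among 20 measured genes next to Hprt, equally many on each side, limma called 0 higher and 5 lower at 24 h. At an unadjusted p under 0.05, 1 was higher and 9 lower, and the median change of the 20 was -0.294. Many of them are microRNA genes in clusters, so they are not independent. The called genes outside these were Gpc3 (-1.05), Ccdc160 (-0.705), Phf6 (-0.674) and Rtl8c (-2.05), all lower. For the neighbours measured, the values argue against a shared rise, but they do not settle it for the whole region. An effect on Hprt alone was not tested.

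X-linked genes were more frequent among called genes than among all tested genes (3.73%). They made up 8.64% of the genes higher and 9.57% of those lower at 12 h, and 5.93% and 7.17% at 24 h (Fisher's exact test, two-sided, adjusted over 6 tests, p = 0.00754, 0.00754, 0.0354 and 7.2e-05). In the controls between day 2.5 and day 3 they made up 4.46% of the higher and 10.3% of the lower genes (adjusted p = 0.613 and 0.0673). With 7 X-linked genes that had been noticed first left out, the share among genes higher at 24 h was 4.27% (17 of 398, Fisher's exact p = 0.501), so an excess among rising genes may rest on the genes that drew attention to it. Without replicate 3 of the induced 24 h group, 22 of 463 higher genes (Fisher's exact p = 0.261) and 30 of 519 lower genes (p = 0.018) were X-linked. Genes are not independent replicates, and this is a hypothesis from the same data.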
